A study of Mus musculus with 20 samples.

How the data were processed

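The samples are embryos and visceral yolk sacs of CD-1 mouse conceptuses grown in whole embryo culture for 24 h, from gestational day 8 to 9, with 0.01% DMSO as the control or with 100 µg/ml mono-2-ethylhexyl phthalate (MEHP). Conceptuses were sorted by the presence of a neural tube defect (NTD). Each tissue has 3 control arrays without NTD, 1 control array with NTD, 3 MEHP arrays without NTD and 3 MEHP arrays with NTD, 20 arrays in all. Whether a sample holds 1 conceptus or several, and from which litters, is not given in the sources used here, so every p-value measures the spread between these samples. Sex-linked genes argue against a single conceptus in 8 of the 20 arrays, which carry both Xist and the Y-linked Ddx3y.

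The deposited expression table holds log2 values for 45141 probe sets, which the submitters' processing notes credit to RMA, with limma and R 2.15.1 also named. The authors' 4 comparison tables (exposure and NTD, for each tissue) hold the same log2 values, a log2 difference of class means, that difference as a ratio, and p-values (p_value: moderated, adjusted over all probe sets, and from an unmoderated test). The deposited ratio equals 2 to the power of the log2 difference. RMA was run by the submitters and not repeated here. Starting signals before RMA were not used here.

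Groups were read from the authors' comparison tables. Each table lists the arrays of 1 tissue, and the deposited log2 difference shows which arrays were averaged as exposed or control, and as with or without NTD. Of 1022 ways to part the 10 arrays of a table, the split used here was the best in all 4 tables. Its largest error over 45141 probe sets was 5.6e-15 to 6.2e-15, against 0.386 to 0.426 for the next best split. A second deposited value table has the same values (largest difference 0.0) under sample headings that would give 13 of the 20 arrays another group and 8 another tissue. The comparison tables were followed, and the headings were run as an alternative. Arrays are numbered within a group in table order. The number is a name only and was not used to pair arrays. Whether an embryo and a yolk sac array at the same place come from the same conceptuses is not given in the sources used here. All control arrays precede all MEHP arrays in the table, so array order and exposure are confounded. Within MEHP all arrays without NTD precede all arrays with NTD in each tissue, so array order and NTD are confounded as well.

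Values were analysed with R 4.3.3, limma 3.58.1 and data.table (version 1.17.8), and figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Of the probe sets, 104 controls and 6670 without a symbol were left out, because they name no gene. The other 38367 have 1 symbol each. Symbols were updated by Entrez identifier for 35403 of these (3025 changed), and the deposited symbol was kept for 2964. Each of 20794 genes was represented by the probe set with the highest mean over the 20 arrays. The median gene has a mean log2 level of 5.72 over the 20 arrays of both tissues (range 2.60 to 13.63). Genes below that median are called dim. Array medians over all probe sets lie between 4.81 and 4.90.

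For comparisons within a tissue, limma fitted 1 mean per group over the tissue's 10 arrays (4 groups), with empirical Bayes variances. The control array with NTD has its own mean and adds nothing to the spread. For differences between tissues, 8 group means were fitted over 20 arrays, which treats embryos and yolk sacs as independent although both were dissected from cultured conceptuses and may share them. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. All fold changes are log2 differences of group means with limma's standard error (SE), and each group has 3 arrays unless stated. The number of arrays limits the precision, and the median SE of a gene was 0.089 in embryo and 0.08 in yolk sac comparisons. The procedure was tested on simulated data with 200 changed genes. It recovered 64.2% of changes of 0.5 log2 units and 98.5% of changes of 1 unit in the embryo design, 79.1% and 97% in the yolk sac design, and 47.8% and 94% for the difference between tissues. It called 10 or 11 of 20594 unchanged genes.

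A set of 35 gene lists, the model, the threshold and the choice of named genes were fixed before the data were examined. Of 1000 list members 984 are measured and 16 are not. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 35 lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list moves in 1 direction without comparing it with other genes, were run beside it. In simulated data, where genes varied independently, camera found the list that had been moved, and 0 of 34 others. This does not show how camera at the preset correlation behaves when list members vary together. The named genes of a comparison are the 12 largest rises and 12 largest falls past the threshold, the 10 smallest p-values where fewer than 10 genes pass, and up to 4 passing members of each list. Where no member of a list passes, up to 2 with the largest change may be named as not passing. For differences between tissues the 6 largest each way were named. A short set of metabolic, methylation, patterning and sex-linked genes was allowed throughout. Genes outside this rule are said to have been chosen after their values were seen.

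Alternatives fixed in advance were quantile normalization, centring each array on its median, leaving out dim genes, eBayes with trend and robust settings, all 20 arrays in 1 fit, only the 6 arrays compared, every probe set tested, an additive model of exposure and NTD, and leaving out each array in turn. Added after seeing the data were cyclic loess (3 iterations), the mean of the nonspecific background probe sets with 16 to 24 G or C bases as a covariate, leaving out 3 arrays with high RNA 3'/5' ratios, groups by the sample headings of the other value table, and the exchange of a control array with and without NTD. Taking values from the other table was dropped because they are identical. Pairing by replicate number was not run because the columns carry no replicate numbers. The array with NTD among the controls of each tissue was compared with the controls without NTD as values, with no test of its own. It was also set against 10000 random lists of like mean level over all 20 arrays of both tissues. Nonspecific probe sets, which match no mouse transcript, were compared between 6 MEHP and 4 control arrays of a tissue by a two-sided exact permutation test over 210 arrangements.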

Results

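Expression of 20794 genes was measured on 20 arrays from cultured mouse conceptuses, 10 from embryos and 10 from visceral yolk sacs, the extraembryonic layer that feeds the embryo at this stage. Each tissue has 3 controls, 3 MEHP samples without NTD, 3 MEHP samples with NTD and 1 control with NTD. The number of arrays limits the precision. Groups follow the authors' own comparison tables, since the sample headings of a second value table would give 13 of the 20 arrays another group. Tissue markers parted the control arrays of both tissues clearly. The neural and stem cell factor Sox2 (1416967_PM_at) had a mean log2 level of 10.37 in embryos and 3.31 in yolk sacs, a difference of 7.06 ± 0.09 (SE, 3 arrays each; adjusted p = 2.64e-18). Cubn (1452270_PM_s_at), the endocytic receptor of the yolk sac endoderm, stood at 4.80 in embryos and 12.60 in yolk sacs (-7.80 ± 0.58, adjusted p = 3.18e-09). Between control tissues 10657 genes differed, 5906 higher in embryo and 4751 higher in yolk sac. The heart genes Myl7 (6.78 ± 0.17) and Tnnt2 (6.19 ± 0.08) and the neural gene Zic1 (6.92 ± 0.12) were among those higher in embryo, and Folr1, the folate receptor (-6.16 ± 0.17), and Afp (-3.96 ± 0.57) among those higher in yolk sac.

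Which embryonic genes differ with MEHP when no NTD is seen was asked by comparing MEHP embryos without NTD with control embryos without NTD (3 arrays each). The imprinted noncoding RNA Kcnq1ot1 (1442029_PM_at) rose from a mean of 6.98 in controls to 8.46 with MEHP (1.48 ± 0.17, adjusted p = 0.00338). Lrp2 (1427133_PM_s_at), which encodes the endocytic receptor megalin needed for forebrain and neural tube development, rose from 6.27 to 7.28 (1.01 ± 0.13, adjusted p = 0.00518). Pax3 (1420389_PM_at), a dorsal neural tube and neural crest factor, rose from 7.45 to 7.94 (0.49 ± 0.07, adjusted p = 0.0074), and the hindbrain gene Hoxa2 (1419602_PM_at) from 6.28 to 7.07 (0.79 ± 0.13, adjusted p = 0.0109). Creb3l3 (1424688_PM_at), a liver and gut lipid regulator, fell from 6.004 to 4.784 (-1.22 ± 0.17, adjusted p = 0.00606). Without any 1 of the 6 arrays Kcnq1ot1, Lrp2, Pax3 and Creb3l3 stayed past the threshold (highest adjusted p 0.0266, 0.0304, 0.0385 and 0.0304). Hoxa2 passed without 5 of the 6 (highest adjusted p 0.0502).

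Direct PPAR targets, the fatty acid genes through which phthalate monoesters act in liver, did not move together in these embryos. Of 39 measured members, Hadhb (0.52 ± 0.10) and Pex11a rose, Creb3l3 fell and 36 did not pass, and 1 rise and 1 fall passed when adjusted over the list alone. The list's median was -0.01 while the test pointed up (adjusted p = 0.508). Cpt1a (0.29 ± 0.11, adjusted p = 0.112), Pdk4 (0.05 ± 0.07, adjusted p = 0.71) and Angptl4 (-0.01 ± 0.14, adjusted p = 0.964) did not pass. Methyltransferase genes did not pass either: Dnmt1 -0.03 (adjusted p = 0.816), Dnmt3a -0.11 (0.373) and Dnmt3b 0.07 (0.562). Of 27 xenobiotic metabolism genes 1 rose and 8 fell, among them Cyp2b10 (-0.56 ± 0.14) and Abcc3 (-0.46 ± 0.08), and 18 did not pass. Adjusted over the list alone it was 1 and 11. The list was not called (median -0.10, adjusted p = 0.0771). Cyp1a1, 1 of the 8 falls (-0.315), stood at 4.067 in controls and 3.752 with MEHP. Nonspecific probe sets stood at 3.918 to 4.048 and 3.704 to 3.801 on these arrays, so Cyp1a1 lay near their level.

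Developmental lists made up most of the 9 lists that camera called in these embryos. None of the 9 held with an estimated correlation (smallest adjusted p 0.131). Of 55 neural tube closure genes 6 rose (among them Lrp2, Pax3, Itgb1, Fgfr1 and Zic5), 0 fell and 49 did not pass. There were 7 rises when adjusted over the list alone (median 0.10, adjusted p = 1.63e-05, and 0.131 with an estimated correlation). Of 28 Hox genes 4 rose (Hoxa2, Hoxd3, Hoxd4 and Hoxa9) and 24 did not pass, with 6 rises and 1 fall when adjusted over the list alone (median 0.16, adjusted p = 0.00106, and 0.233 with an estimated correlation). Collagen and mesenchyme genes rose in 5 of 32 cases, such as Col11a1 (0.76 ± 0.12) and Col1a1 (0.67). It was 6 when adjusted over the list alone (median 0.14, adjusted p = 0.00101, and 0.422 with an estimated correlation). Among 22 parietal endoderm and basement membrane genes, Krt19 (0.54) and Lamb1 (0.35) rose and Hspg2 fell. There were 5 rises and 1 fall when adjusted over the list alone (median 0.17, adjusted p = 0.00112, and 0.349 with an estimated correlation).

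The other 5 calls, with larger p-values, were for neuronal, imprinted, cardiac, neural progenitor and trophoblast genes. Neuronal differentiation genes had 2 rises, Neurog1 (0.70 ± 0.15) and Pou4f1 (0.37), and 1 fall, Nhlh1 (-0.41), among 29. It was 3 and 1 adjusted over the list alone (median 0.10, adjusted p = 0.0114, and 0.422 with an estimated correlation). Imprinted genes had 2 rises of 30, Kcnq1ot1 and Peg12 (0.79 ± 0.19), and 2 adjusted over the list alone (median 0.07, adjusted p = 0.0394, and 0.485 with an estimated correlation). Cardiac genes had 2 rises of 31, Tnnt2 (0.39 ± 0.07) and Cryab, and 2 adjusted over the list alone (median 0.08, adjusted p = 0.0481, and 0.434 with an estimated correlation). Neural progenitor genes had 2 rises of 33, Sox1 (0.59 ± 0.15) and Sox11 (0.35), and 1 fall, Dmbx1. It was 2 and 1 adjusted over the list alone (median 0.09, adjusted p = 0.0481, and 0.349 with an estimated correlation). Trophoblast and decidua genes, which stand for tissue outside the embryo, had 0 rises and 4 falls of 24 (Prl7b1 -0.50 ± 0.08, Pgr, Ctsj and Psg21). There were 6 falls adjusted over the list alone (median -0.14, adjusted p = 0.0481, and 0.34 with an estimated correlation). Their levels are near the floor of the arrays, with Prl7b1 at 3.795 in controls. The other 26 lists were not called (medians -1.10 to 0.10). One of these is the visceral endoderm list, a mark of yolk sac tissue. Its median level (not its change) was 5.58 in control embryo 2 and 5.57 in MEHP embryo 3 against 4.68 to 5.13 in the other 8 embryo arrays. Another is the sex-linked list. Mean Ddx3y was 5.071 in MEHP and 6.358 in control embryos without NTD, mean Xist was 11.767 and 9.617, and neither passed.

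Call by call, leaving out 1 array ended some of these lists, while neural tube closure, Hox and parietal endoderm genes were called under each of the 6. Neural progenitor genes ended without control 1 (adjusted p = 0.0512), control 2 (0.0789), control 3 (0.0614), MEHP 1 (0.0834) or MEHP 3 (0.0724). Trophoblast genes ended without control 1 (0.0821), control 2 (0.0789), MEHP 1 (0.0707) or MEHP 2 (0.07). Cardiac genes ended without control 3 (0.138), MEHP 1 (0.0671) or MEHP 3 (0.0724), and imprinted genes without control 3 (0.177) or MEHP 2 (0.0566). Mesenchyme genes ended without control 3 (0.1) and neuronal genes without MEHP 1 (0.0842). After cyclic loess 4 of the 9 were called: neural tube closure, Hox, mesenchyme and parietal endoderm genes.

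Across all genes 2021 passed in MEHP embryos, 794 rising and 1227 falling (39.3% rising), and 29.2% rose under quantile normalization. Expressed-sequence-tag and predicted transcripts made up 205 of the rises and 311 of the falls, and D10Ertd755e (1438810_PM_at, 2.03 ± 0.21) was the largest rise. Other large rises were Mid1 (1.65 ± 0.37) and the muscle factor Myf5 (1.17 ± 0.22), and other large falls were Csf2rb (-0.87 ± 0.15) and Apoh (-0.86 ± 0.13). Dim genes made up 1011 of the falls and 213 of the rises, and the 9 probe sets with 16 to 24 G or C bases that match no mouse transcript were lower by 0.22 log2 units in MEHP embryo arrays (-0.221, 3.65 to 3.801 against 3.91 to 4.05 in the controls; 6 against 4 arrays, two-sided exact permutation p = 0.00476). Without dim genes 488 passed, and after cyclic loess 1094 (982 of them among the 2021). The level of these nonspecific probe sets parts MEHP from control arrays by itself, so a fit with it cannot tell it from exposure. With it as a covariate none (0) passed, and 1522 genes have an unadjusted p below 0.05 by limma. It was 612 without control 1, 1072 without control 2, 549 without MEHP 1, 286 without MEHP 2 and 414 without MEHP 3. It was 3309 without the arrays with high RNA 3'/5' ratios, here control 3 (Gapdh 0.31, Actb 0.88) and MEHP with NTD 1 (0.35 and 0.86).

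**Figure D1:**
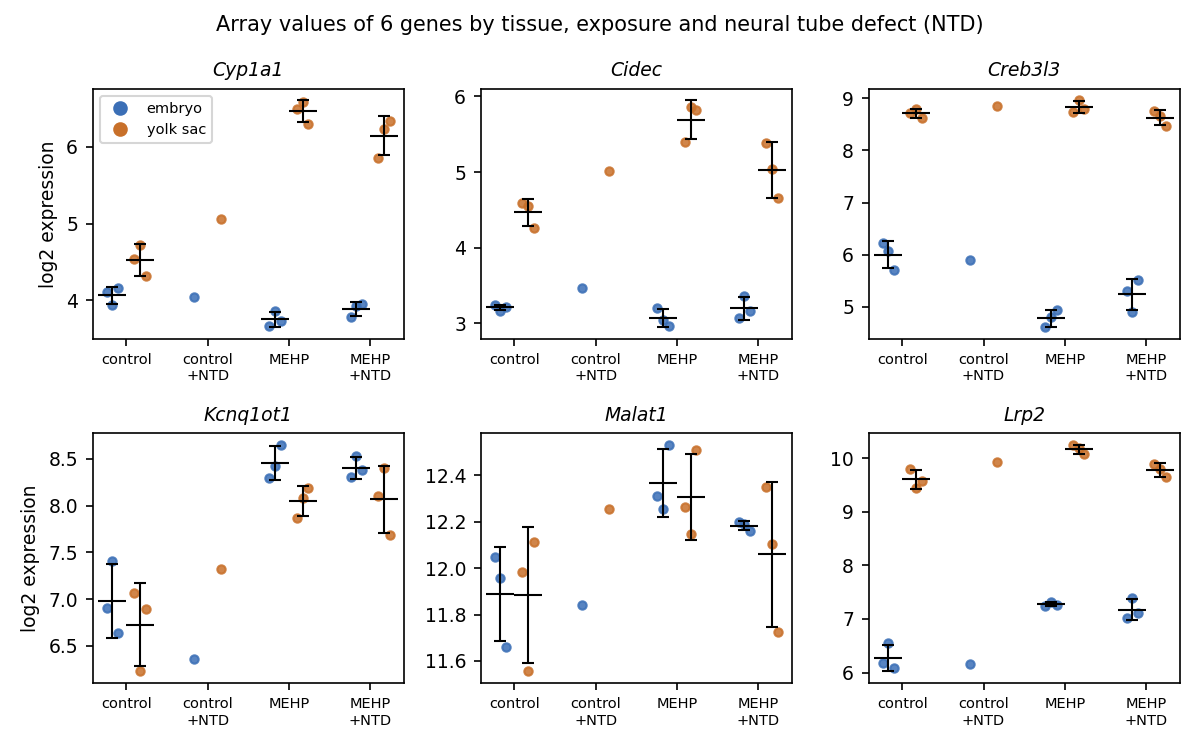
Log2 expression (vertical axis) of 6 genes by group (horizontal axis) in embryos (blue) and yolk sacs (orange), where points are arrays, black dashes are group means and bars are standard deviations. Cyp1a1 stands at 6.46 in MEHP yolk sacs and 4.53 in control yolk sacs, and Kcnq1ot1 is higher with MEHP in both tissues (8.46 against 6.98 in embryos, 8.05 against 6.73 in yolk sacs).

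Which embryonic genes differ with an NTD among exposed conceptuses was asked by comparing MEHP embryos with and without NTD (3 arrays each). Lhx9 (1419324_PM_at), a LIM homeobox gene of the developing brain and limb, fell from 6.39 without NTD to 4.67 with NTD (-1.72 ± 0.20, adjusted p = 0.0441). The axon guidance receptor gene Epha3 (1455426_PM_at) fell from 6.46 to 5.47 (-0.99 ± 0.12, adjusted p = 0.0441), and Prrx1 (1425526_PM_a_at), a gene of neural crest and mesenchyme, from 8.12 to 7.52 (-0.60 ± 0.07, adjusted p = 0.0441). Genes of the amino acid and endoplasmic reticulum stress response rose: Atf5 (1425927_PM_a_at) from 7.18 to 8.08 (0.89 ± 0.11, adjusted p = 0.0443) and Ddit3 (1417516_PM_at) from 6.47 to 6.96 (0.49 ± 0.06, adjusted p = 0.0443). These 5 were all that passed, 2 up and 3 down, with 1177 genes at an unadjusted p below 0.05. Next in order, and not passing, came Dcx (-0.63 ± 0.09, adjusted p = 0.0509), Prcp (0.74 ± 0.10, 0.0509), Nefm (-1.08 ± 0.15, 0.0549) and Mab21l1 (-0.47, 0.0562). In the single control embryo with NTD, Lhx9 (6.215 against a mean of 5.586), Prrx1 (8.08 against 7.68) and Ddit3 (6.63 against 6.49) lay above all 3 controls, and Atf5 (7.41 against 7.32) and Epha3 (6.41 against 6.36) within their range.

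Neuronal differentiation genes were lower as a group in MEHP embryos with NTD, and this list alone was called by camera at both correlations. Of 29 members 0 passed over all genes, while 1 rise and 19 falls passed when adjusted over the list alone. Among these are Nefl (-1.11 ± 0.17), Nefm and Nhlh2 (-1.08 ± 0.18), which did not pass over all genes. The median was -0.48 (26 members lower, 3 higher; adjusted p = 1.04e-24, and 0.0444 with an estimated correlation). The list's median level was 5.94 to 6.08 in MEHP embryos with NTD and 6.15 to 6.53 in all other embryo arrays. Neural progenitor genes (median -0.03, adjusted p = 0.504) and neural tube closure genes (median 0.01, mean -0.03, adjusted p = 0.652) were not called. In the single control embryo with NTD the neuronal list lay 0.16 above the controls' mean (0.156, above 99.92% of random lists of like mean level over both tissues). Random genes need not vary together as list members may, and this is 1 array, so the percentile is no test.

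Stress response and heart genes were higher in the same embryos with NTD. Of 34 unfolded protein and amino acid stress genes 1 rose over all genes (Ddit3) and 14 adjusted over the list alone, with 0 falls (median 0.23, adjusted p = 1.53e-17, and 0.0898 with an estimated correlation). Of 31 cardiac genes 0 passed over all genes, with Tnni3 the largest rise (0.65 ± 0.14, adjusted p = 0.266). Adjusted over the list alone 12 rose and 0 fell (median 0.23, adjusted p = 3.66e-14, and 0.0599 with an estimated correlation). Of 22 Wnt response genes 0 passed and 2 rose adjusted over the list alone (median 0.16, adjusted p = 0.00192, and 0.244 with an estimated correlation). Of 23 neural crest genes Prrx1 fell, over all genes and adjusted over the list alone, and 22 did not pass (median -0.07, adjusted p = 0.0364, and 0.188 with an estimated correlation). The neural crest call ended without MEHP 1 (adjusted p = 0.105), MEHP 2 (0.126) or MEHP with NTD 3 (0.0747), and after cyclic loess. PPAR targets were not called (median -0.07, adjusted p = 0.0661), nor were the other 29 lists (medians -0.10 to 0.07).

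The count of 5 depends on which arrays are included, and ranged from 0 to 7 with 1 left out. It was 0 without MEHP 1, MEHP 2 or MEHP 3, and 1 without MEHP with NTD 1 or MEHP with NTD 3. With 1 array left out, Lhx9 ranged from -1.95 to -1.48 and passed in 2 of 6 fits (adjusted p = 0.00762 to 0.233), Epha3 passed in 1 (0.0286 to 0.233), and Prrx1, Atf5 and Ddit3 passed in 0. Counts were 0 under quantile normalization, without dim genes, with the 6 arrays alone or with the nonspecific level as a covariate, 8 with trend and robust settings and 20 with all 20 arrays in 1 fit. It was 2 without the arrays with high RNA 3'/5' ratios, here MEHP with NTD 1.

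**Figure D2:**
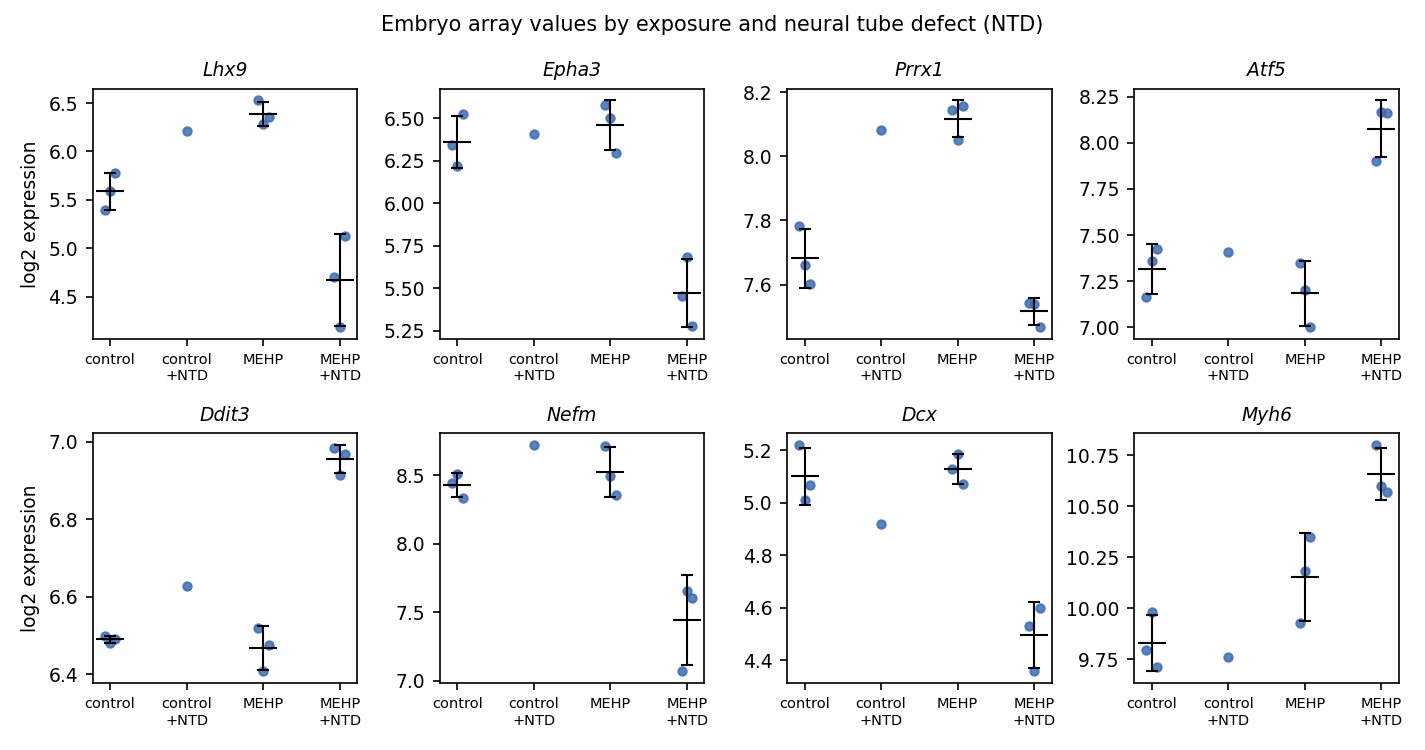
Log2 expression (vertical axis) of 8 genes by group (horizontal axis) in embryos, where points are arrays, black dashes are group means and bars are standard deviations. Lhx9 (4.67 against 6.39), Epha3 (5.47 against 6.46) and Nefm (7.44 against 8.52) are lower in MEHP embryos with NTD than in those without, and Atf5 is higher (8.08 against 7.18).

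How embryos with both exposure and NTD differ from unexposed embryos was asked by comparing MEHP embryos with NTD and control embryos without NTD (3 arrays each). The heart genes Tnnt2 (1418726_PM_a_at) rose from 10.14 to 10.86 (0.72 ± 0.07, adjusted p = 0.00249) and Myh6 (1448826_PM_at) from 9.83 to 10.66 (0.83 ± 0.12, adjusted p = 0.00802). The neurofilament genes Nefl (1426255_PM_at) fell from 8.21 to 7.08 (-1.14 ± 0.17, adjusted p = 0.00939) and Nefm (1422520_PM_at) from 8.43 to 7.44 (-0.99 ± 0.15, adjusted p = 0.00952). Csf2rb (1455660_PM_at), a blood cell cytokine receptor gene, fell from 7.14 to 5.43 (-1.71 ± 0.15, adjusted p = 0.00249). Mid1 (1438239_PM_at) was the largest rise past the threshold (2.147 ± 0.37, adjusted p = 0.0153), followed by D10Ertd755e (2.09). Tnnt2, Myh6, Nefl, Nefm and Csf2rb passed without any 1 of the 6 arrays (highest adjusted p 0.0144, 0.0335, 0.0356, 0.036 and 0.0141), and Mid1 passed in 4 of 6 fits (0.00184 to 0.0523). This comparison shares its control arrays with the one on MEHP alone and its MEHP arrays with the one on NTD, so the results are not independent.

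Stress response genes rose in these embryos in 10 of 34 cases, among them Trib3 (0.79 ± 0.15), Cebpb (0.71 ± 0.12), Psat1 (0.64 ± 0.11) and Stc2 (0.65 ± 0.12), while Fgf21 fell (-0.33) and 23 did not pass. There were 13 rises and 1 fall adjusted over the list alone (median 0.30, adjusted p = 3.56e-11, and 0.17 with an estimated correlation). Cardiac genes rose in 11 of 31 cases, and in 16 with 1 fall adjusted over the list alone (median 0.29, adjusted p = 5.58e-11, and 0.108 with an estimated correlation). Neuronal genes fell in 8 of 29 cases, such as Neurod1 (-0.81 ± 0.19). There were 10 falls adjusted over the list alone (median -0.22, adjusted p = 0.000626, and 0.266 with an estimated correlation). Neural tube closure genes rose in 3 of 55 cases, Lrp2 (0.91 ± 0.13), Fgfr1 and Dvl2, and in 2 adjusted over the list alone (median 0.10, adjusted p = 1.77e-05, and 0.108 with an estimated correlation). Macrophage genes fell in 2 of 21 cases, Csf1r (-0.67 ± 0.11) and Mpo (-0.40), and in 2 adjusted over the list alone (median -0.19, adjusted p = 0.0121, and 0.26 with an estimated correlation). Of 39 PPAR targets 0 rose and 5 fell, among them Plin2 (-0.34 ± 0.06, adjusted p = 0.0196) and Lpl (-0.36 ± 0.09). Adjusted over the list alone there were 1 rise and 6 falls, and the list was not called (median -0.04).

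A further 6 lists were called upward in MEHP embryos with NTD. Hox genes had 2 rises, Hoxb1 (0.50) and Hoxd4, and 3 adjusted over the list alone (median 0.17, adjusted p = 0.000925, and 0.17 with an estimated correlation). Parietal endoderm genes had 5 rises and 1 fall, and 6 and 1 adjusted over the list alone (median 0.09, adjusted p = 0.00534, and 0.316 with an estimated correlation). Mesenchyme genes had 5 rises, and 7 with 2 falls adjusted over the list alone (median 0.04, adjusted p = 0.012, and 0.458 with an estimated correlation). Wnt response genes had 0 members past either way (median 0.12, adjusted p = 0.00342, and 0.26 with an estimated correlation). Methylation and one-carbon genes had 1 rise and 0 adjusted over the list alone (median 0.11, adjusted p = 0.00534, and 0.224 with an estimated correlation). Heat shock genes had 1 rise (Hspa8) by both counts (median 0.04, adjusted p = 0.012, and 0.373 with an estimated correlation). The other 24 lists were not called (medians -1.10 to 0.12). Mesenchyme (0.323) and parietal endoderm genes (0.0513) ended without control 3, and heat shock genes without MEHP with NTD 1 (0.0682). After cyclic loess 6 of the 11 lists were called: stress response, cardiac, neuronal, neural tube closure, Hox and Wnt response genes.

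In all, 1549 genes passed in MEHP embryos with NTD, 667 up and 882 down, of which 163 and 208 are expressed-sequence-tag or predicted transcripts. The count was 511 without dim genes, 348 with the 6 arrays alone, 795 after cyclic loess (718 of them among the 1549) and 0 with the level of the nonspecific probe sets as a covariate (1576 genes at an unadjusted p below 0.05 by limma). It was 397 without control 1, 692 without control 2, 1030 without MEHP with NTD 1, 270 without MEHP with NTD 2 and 509 without MEHP with NTD 3. Since the nonspecific level parts exposed from control arrays, the count of 0 under that covariate cannot tell it from exposure.

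Which yolk sac genes differ with MEHP when no NTD is seen was asked by comparing MEHP yolk sacs without NTD with control yolk sacs without NTD (3 arrays each). Cyp1a1 (1422217_PM_a_at), the classic target of the aryl hydrocarbon receptor, rose from 4.53 in controls to 6.46 with MEHP (1.94 ± 0.14, 3.82-fold, adjusted p = 0.00129). Cidec (1452260_PM_at), a lipid droplet gene and PPAR target, rose from 4.47 to 5.69 (1.22 ± 0.18, adjusted p = 0.0333), and Kcnq1ot1 from 6.73 to 8.05 (1.32 ± 0.22, adjusted p = 0.0444). Iapp (1423509_PM_a_at) fell from 5.52 to 4.37 (-1.15 ± 0.12, adjusted p = 0.028), and Pdx1 (-0.60 ± 0.08), Ucp3 (-0.53 ± 0.07) and Dll1 (-0.52 ± 0.07) fell with the same adjusted p of 0.028. Of the abundant genes, Gstp1 fell from 11.49 to 11.09 (-0.40 ± 0.06, adjusted p = 0.0398) and Hspb1 from 10.70 to 10.18 (-0.52 ± 0.09, adjusted p = 0.043). Afp, the main product of this tissue, did not pass (0.04 ± 0.06, adjusted p = 0.792). Without any 1 of the 6 arrays Cyp1a1 passed (adjusted p = 0.00338 to 0.019, and 0.231 with the nonspecific level as a covariate, over all alternatives 4.08e-07 to 0.231). Iapp passed in 1 of the 6 such fits, and Cidec, Kcnq1ot1, Pdx1 and Ucp3 in 0 (highest adjusted p 0.139, 0.155, 0.114 and 0.114). Because the nonspecific level parts MEHP from control yolk sac arrays, the fit with it as a covariate cannot tell it from exposure.

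PPAR targets as a list were called upward in MEHP yolk sacs, although Cidec rose, Ucp3 fell and 37 of 39 did not pass. Adjusted over the list alone 5 rose and 2 fell (median 0.06, adjusted p = 0.0283, and 0.729 with an estimated correlation). Cpt1a (0.14 ± 0.10, adjusted p = 0.501) and Angptl4 (-0.10 ± 0.11, adjusted p = 0.704) did not pass. Cholesterol synthesis genes lay higher in 23 of 25 cases (median 0.18, adjusted p = 1.51e-05, and 0.729 with an estimated correlation). By either count 0 passed. Visceral endoderm genes had 0 past, and 1 rise adjusted over the list alone (39 members, median 0.05, adjusted p = 0.00138, and 0.729 with an estimated correlation). Of 27 xenobiotic metabolism genes Cyp1a1 alone passed, with 2 rises and 3 falls adjusted over the list alone, and the list's median was 0.00 (-0.001).

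Hedgehog pathway genes lay lower in MEHP yolk sacs in all 21 cases, with 0 past by either count, Gli2 (-0.45, adjusted p = 0.222) being the lowest. The list median was -0.13 (adjusted p = 0.0095, and 0.407 with an estimated correlation). Trophoblast genes, which stand for tissue outside the yolk sac, had 0 past the threshold (24 members, median -0.15, adjusted p = 0.0095, and 0.729 with an estimated correlation). Antioxidant enzyme genes (24 members, median 0.06, adjusted p = 0.0115, and 0.407 with an estimated correlation) and endocytosis and lysosome genes (36 members, median 0.05, adjusted p = 0.0272, and 0.729 with an estimated correlation) had 0 past as well. None of the 7 calls held with an estimated correlation or with fry, and the other 28 lists were not called (medians -0.84 to 0.04). Endocytosis genes ended without control 2 (adjusted p = 0.202), control 3 (0.0998) or MEHP 1 (0.0764), and without control 3 the Hedgehog (0.0536) and PPAR target lists (0.0998) ended too. After cyclic loess 3 of the 7 were called: cholesterol, visceral endoderm and Hedgehog genes.

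In all, 65 genes passed in MEHP yolk sacs, 40 up and 25 down (61.5% up, and 42.7% under quantile normalization), and 23 of the rises are expressed-sequence-tag or predicted transcripts. The nonspecific probe sets with 16 to 24 G or C bases were lower in the MEHP arrays of this tissue as well (-0.194, 3.70 to 3.83 against 3.87 to 4.08; 6 against 4 arrays, two-sided exact permutation p = 0.00476). The count was 2 without control 1 or MEHP 1, and 1 without control 2, control 3, MEHP 2 or MEHP 3. It was 28 without dim genes, 199 with trend and robust settings, 191 with all 20 arrays in 1 fit, 0 with the nonspecific level as a covariate and 2 with control 3 and the control with NTD exchanged. It was 1 without control 2, the array with high RNA 3'/5' ratios (Gapdh 0.48, Actb 0.96). Since the nonspecific level parts MEHP from control arrays here too, the count of 0 under that covariate cannot tell it from exposure.

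Which yolk sac genes differ with an NTD of the embryo among exposed conceptuses was asked by comparing MEHP yolk sacs with and without NTD (3 arrays each). No gene passed by limma (0 of 20794, smallest adjusted p 0.0878), and 2002 had an unadjusted p below 0.05. The smallest p-values, each with an adjusted p of 0.0878, belonged to genes that include Cndp1 (1455561_PM_at, 5.96 against 5.24, 0.72 ± 0.10), Pcdh18 (0.62 ± 0.09), Robo1 (0.61 ± 0.09), the Hedgehog effector Gli3 (0.48 ± 0.07) and Pdxk (-0.45 ± 0.06). Larger but more variable were Sfrp1 (1.26 ± 0.34, adjusted p = 0.272) and Fabp4 (-0.82 ± 0.22, adjusted p = 0.265), and Cidec lay at 5.03 against 5.69 (-0.66 ± 0.18, adjusted p = 0.278). The count was 1 without MEHP 3, 13 with trend and robust settings, 30 with all 20 arrays in 1 fit and 2 in the additive model.

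Endocytosis and visceral endoderm lists were called downward in yolk sacs of exposed conceptuses with NTD, and BMP, retinoic acid and mesenchyme lists upward. Camera called 15 of 35 lists, and none held with an estimated correlation (smallest adjusted p 0.214). Each of the 15 had 0 members past over all genes, so the counts here are those adjusted over the list alone. Endocytosis and lysosome genes had 5 falls of 36, such as Glb1 (-0.35 ± 0.07, adjusted p = 0.185 over all genes) and Mcoln1 (-0.33 ± 0.07, 0.196). Their median was -0.09 (adjusted p = 3.68e-09, and 0.214 with an estimated correlation). Visceral endoderm genes lay lower in 34 of 39 cases with 0 past (median -0.08, adjusted p = 3.46e-06, and 0.304 with an estimated correlation). PPAR targets had 1 rise and 5 falls (median -0.07, adjusted p = 0.00279, and 0.304 with an estimated correlation). BMP response genes had 5 rises of 23, Bmp2 (0.53 ± 0.12) among the largest (median 0.15, adjusted p = 0.0016, and 0.214 with an estimated correlation). Retinoic acid genes had 4 rises of 22 (median 0.18, adjusted p = 0.00175, and 0.304 with an estimated correlation). Hox genes had 3 of 28 (median 0.08, adjusted p = 0.00853, and 0.394 with an estimated correlation) and mesenchyme genes 0 of 32 (median 0.16, adjusted p = 0.000285, and 0.272 with an estimated correlation).

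Further shifts in the same yolk sacs were downward for cholesterol genes (median -0.07, adjusted p = 0.013, and 0.502 with an estimated correlation) and fatty acid synthesis genes (1 fall, median -0.05, adjusted p = 0.0168, and 0.33 with an estimated correlation). Upward shifts were called for neural crest genes (3 rises, median 0.11, adjusted p = 0.0182, and 0.214 with an estimated correlation), cardiac genes (2 rises, median 0.12, adjusted p = 0.0375, and 0.272 with an estimated correlation) and parietal endoderm genes (1 rise, median 0.07, adjusted p = 0.0175, and 0.214 with an estimated correlation). Cell cycle (median 0.05, adjusted p = 0.0143, and 0.476 with an estimated correlation) and endothelial genes (median 0.09, adjusted p = 0.0182, and 0.476 with an estimated correlation) had 0 past. Primitive erythroid genes, a mark of blood in the yolk sac, lay higher in 30 of 33 cases (median 0.23, adjusted p = 0.0168, and 0.731 with an estimated correlation), and their median level varied from 7.35 in control 1 to 9.27 in MEHP with NTD 1. The other 20 lists were not called (medians -0.05 to 0.10).

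Of these 15 yolk sac lists, endocytosis, visceral endoderm, PPAR target, BMP, retinoic acid and mesenchyme genes were called without any 1 of the 6 arrays. Erythroid genes ended without MEHP 1 (adjusted p = 0.316), MEHP 3 (0.324) or MEHP with NTD 1 (0.607, direction reversed). Cholesterol genes ended without MEHP 1 (0.153), MEHP 3 (0.0519), MEHP with NTD 2 (0.0908) or 3 (0.285), and cell cycle genes without MEHP 1 (0.0533), MEHP 3 (0.0519) or MEHP with NTD 3 (0.115). Cardiac genes ended without MEHP 1 (0.0533), MEHP 2 (0.107) or MEHP with NTD 1 (0.264), and endothelial genes without MEHP 3 (0.346) or MEHP with NTD 2 (0.0786) or 3 (0.231). Fatty acid synthesis genes ended without MEHP 1 (0.148) or MEHP with NTD 3 (0.103), and parietal endoderm genes without MEHP 2 (0.0531) or MEHP with NTD 1 (0.0516). Neural crest genes ended without MEHP 3 (0.115) or MEHP with NTD 1 (0.054), and Hox genes without MEHP with NTD 3 (0.137).

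**Figure D3:**
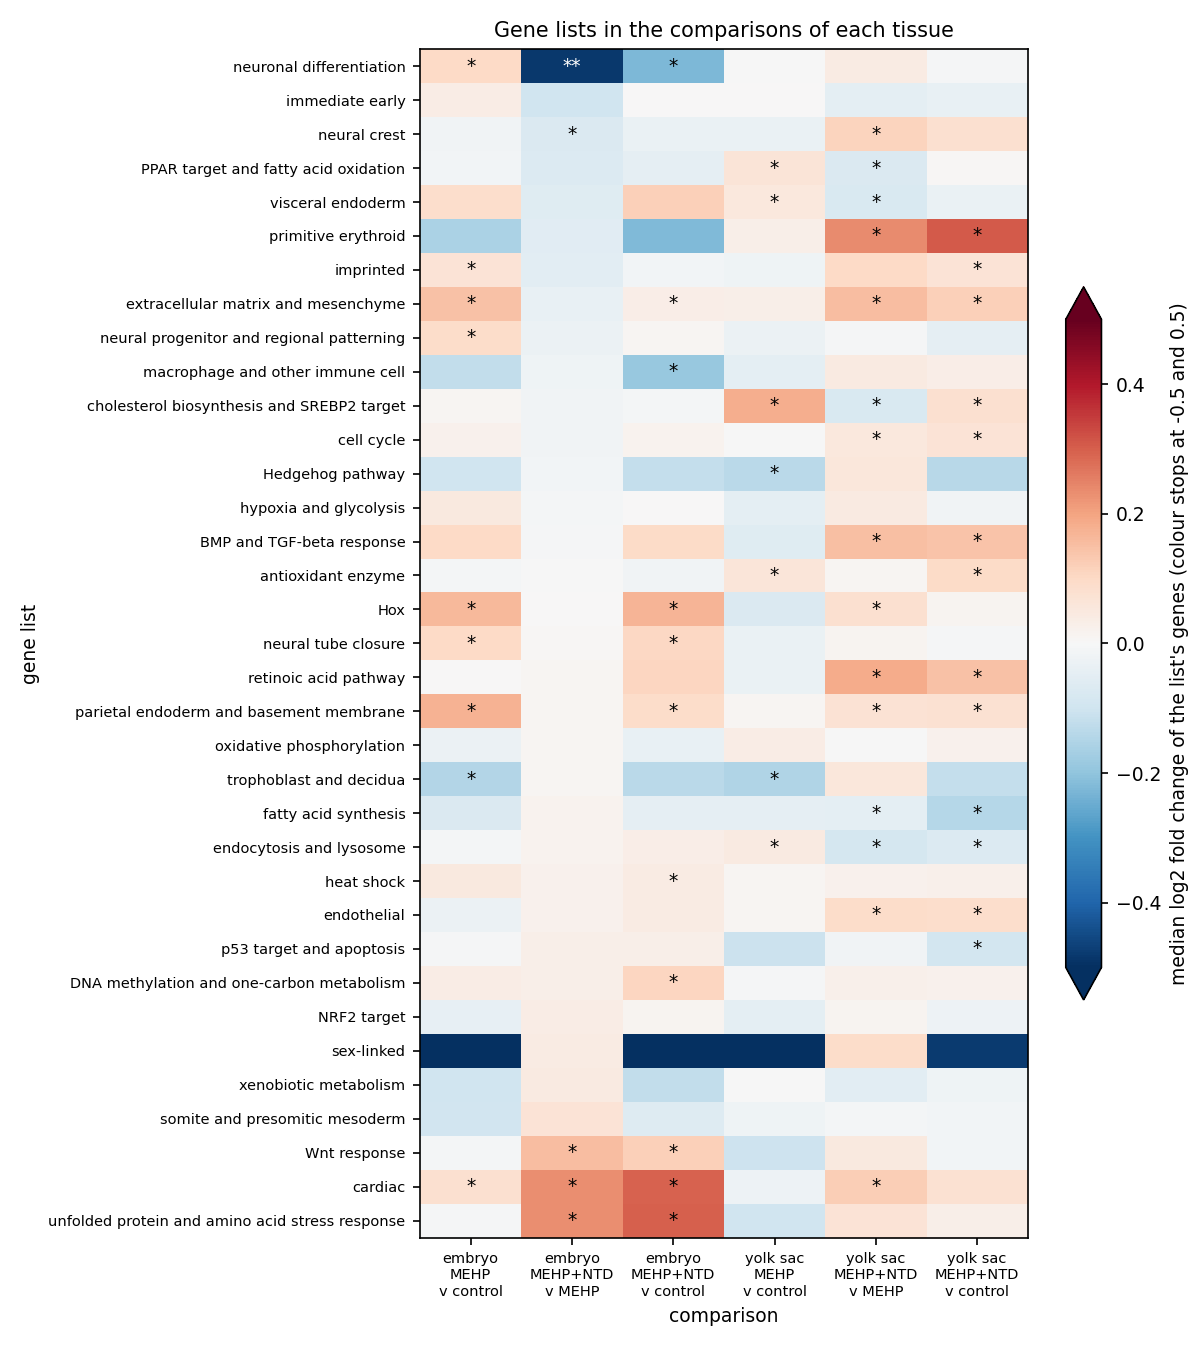
Median log2 fold change (colour, ending at -0.5 and 0.5) of 35 gene lists (vertical axis) in 6 comparisons (horizontal axis), ordered by the comparison of MEHP embryos with and without NTD, where * marks a camera adjusted p below 0.05 at the preset correlation and ** one that also holds with an estimated correlation. The neuronal list in MEHP embryos with NTD against those without (median -0.48) carries the only **.

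How yolk sacs with both exposure and NTD differ from unexposed yolk sacs was asked by comparing MEHP yolk sacs with NTD and control yolk sacs without NTD (3 arrays each). Cyp1a1 rose from 4.53 to 6.14 (1.62 ± 0.14, adjusted p = 0.00339), Cndp1 from 4.84 to 5.96 (1.11 ± 0.10, adjusted p = 0.00339) and the imprinted noncoding RNA Airn (1451634_PM_at) from 7.14 to 7.94 (0.80 ± 0.13, adjusted p = 0.0281). Kcnq1ot1 rose from 6.73 to 8.07 (1.34 ± 0.22, adjusted p = 0.0277). Iapp fell from 5.52 to 4.16 (-1.36 ± 0.12, adjusted p = 0.00339) and Gatm (1423569_PM_at), a creatine synthesis gene, from 5.84 to 5.05 (-0.79 ± 0.10, adjusted p = 0.0143). Cyp1a1, Cndp1 and Iapp passed without any 1 of the 6 arrays (highest adjusted p 0.0238, 0.0298 and 0.0266), and Kcnq1ot1 passed in 2 of 6 fits (0.032 to 0.0754). The control arrays are those of the comparison on MEHP alone.

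BMP response genes and p53 target and apoptosis genes were among the 13 lists called in these yolk sacs. None of the 13 held with an estimated correlation (smallest adjusted p 0.337). BMP response genes rose in 2 of 23 cases, Msx1 (0.61 ± 0.11) and Bambi (0.57 ± 0.09), and in 2 adjusted over the list alone (median 0.14, adjusted p = 0.016, and 0.337 with an estimated correlation). Of the p53 target and apoptosis genes, Cdkn1a (-0.38 ± 0.08, adjusted p = 0.0475) and Bcl2 (-0.46 ± 0.07) fell and 28 of 30 did not pass. Adjusted over the list alone 6 fell (median -0.09, adjusted p = 0.0196, and 0.417 with an estimated correlation). Cell cycle genes rose in 2 of 35 cases, Ccnb2 (0.37 ± 0.06) and Mki67 (0.34 ± 0.07), with 2 rises and 1 fall adjusted over the list alone (median 0.07, adjusted p = 0.0339, and 0.657 with an estimated correlation). Imprinted genes rose in 2 of 30 cases, Kcnq1ot1 and Airn, by both counts (median 0.07, adjusted p = 0.0196, and 0.538 with an estimated correlation). Antioxidant genes rose in 1 of 24 cases, Glrx3 (median 0.09, adjusted p = 0.0186, and 0.337 with an estimated correlation). Endothelial genes rose in 1 of 30, Fli1 (0.46), by both counts (median 0.09, adjusted p = 0.0449, and 0.608 with an estimated correlation).

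The other 7 called lists had 0 members past over all genes. Retinoic acid genes had 2 rises adjusted over the list alone (median 0.15, adjusted p = 0.00667, and 0.417 with an estimated correlation). Fatty acid synthesis genes had 1 fall of 20 (median -0.14, adjusted p = 0.0144, and 0.417 with an estimated correlation) and endocytosis genes 4 falls (median -0.07, adjusted p = 0.0429, and 0.608 with an estimated correlation). Mesenchyme (median 0.12, adjusted p = 0.00667, and 0.417 with an estimated correlation), parietal endoderm (0.07, 0.02 and 0.337) and cholesterol genes (0.08, 0.0429 and 0.839) were higher as lists. Erythroid genes lay higher in 29 of 33 cases (median 0.31, adjusted p = 0.0186, and 0.863 with an estimated correlation). The other 22 lists were not called (medians -0.48 to 0.08). Mesenchyme, fatty acid synthesis and retinoic acid genes were called without any 1 array. Without control 1 the cell cycle (0.102), endocytosis (0.357) and erythroid (0.382) lists ended, and without control 2 imprinted genes (0.0918). Without control 3 it was the cell cycle (0.0961), cholesterol (0.481), endothelial (0.157) and erythroid (0.0655) lists. Without MEHP with NTD 1 the antioxidant (0.0784), BMP (0.0535), cholesterol (0.598), imprinted (0.113), p53 (0.0535), parietal endoderm (0.0535) and erythroid (0.849) lists ended. Without MEHP with NTD 2 it was endocytosis (0.0589) and endothelial genes (0.12), and without MEHP with NTD 3 cell cycle (0.135), endocytosis (0.135) and endothelial genes (0.188). After cyclic loess 8 of the 13 were called.

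In all, 494 genes passed in MEHP yolk sacs with NTD, 291 up and 203 down (58.9% up, and 38.7% under quantile normalization). The count was 15 with the 6 arrays alone, 1 with the nonspecific level as a covariate, 23 with control 3 and the control with NTD exchanged and 32 without control 2, the array with high RNA 3'/5' ratios. It was 181 without control 1, 32 without control 2, 18 without control 3, 192 without MEHP with NTD 1, 99 without MEHP with NTD 2 and 31 without MEHP with NTD 3. Since the nonspecific level parts exposed from control arrays, the count of 1 under that covariate cannot tell it from exposure.

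Whether MEHP acts on other genes in embryo than in yolk sac was asked by testing the difference of its effects in the samples without NTD (12 arrays in 4 groups). Cyp1a1 rose in yolk sacs, while in embryos it lay near the level of the nonspecific probe sets (3.75 with MEHP and 4.07 in controls, against 3.704 to 3.801 and 3.918 to 4.048), so the difference (-2.25 ± 0.17, adjusted p = 8.11e-06) rests mainly on the rise in yolk sacs. Creb3l3 went from 6.004 to 4.784 in embryos and from 8.72 to 8.83 in yolk sacs (-1.33 ± 0.20, adjusted p = 0.0207), and Cidec from 3.21 to 3.07 and from 4.47 to 5.69 (-1.37 ± 0.22, adjusted p = 0.0237). Robo2 (1458229_PM_at, 1.05 ± 0.16, adjusted p = 0.0207) and Myh3 (1427115_PM_at, 0.84 ± 0.11, adjusted p = 0.00786) had the larger effect in embryos. Cidec in embryos and Robo2 in yolk sacs (3.23 and 3.24) lay below the nonspecific probe sets of the same arrays with and without MEHP, so a fall could not be seen there. Robo2 lay below them in control embryos too (3.769). In all 16 genes differed, 6 with the higher effect in embryo and 10 with the higher effect in yolk sac. Cyp1a1 passed without any 1 of the 12 arrays (highest adjusted p 7.5e-05), Creb3l3 in 5 of the 12 fits and Cidec in 4. The count was 3 without embryo MEHP 2, yolk sac control 2, yolk sac MEHP 2 or yolk sac MEHP 3, 4 without embryo control 1, 5 without yolk sac control 1, 7 without yolk sac control 3 or yolk sac MEHP 1, and 9 without embryo MEHP 3. It was 259 without embryo control 3 and 144 without the arrays with high RNA 3'/5' ratios.

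Whether an NTD goes with other genes in embryo than in yolk sac was asked in the same way within MEHP (12 arrays in 4 groups). Lhx9 went from 6.39 to 4.67 in embryos and from 3.43 to 3.35 in yolk sacs (difference -1.65 ± 0.22, adjusted p = 0.0137), Epha3 from 6.46 to 5.47 and from 3.27 to 3.44 (-1.15 ± 0.16, adjusted p = 0.0137), and Zfp462 (1456789_PM_at) from 10.52 to 10.33 and from 7.45 to 7.91 (-0.65 ± 0.10, adjusted p = 0.0368). These 3 were all that passed. In yolk sacs Lhx9 and Epha3 lay below the nonspecific probe sets of the same arrays (3.70 to 3.83), so a fall with NTD could not be seen there and the difference rests on the embryos. Neuronal genes were lower with NTD in embryos relative to yolk sacs (29 members, 0 past, 2 higher and 18 lower adjusted over the list alone, median -0.51, adjusted p = 3.73e-18, and 0.00536 with an estimated correlation). So were neural crest genes (23 members, 0 past, 5 lower adjusted over the list alone, median -0.26, adjusted p = 0.000197, and 0.0102 with an estimated correlation). In yolk sacs 21 of the 29 and 20 of the 23 lay above the nonspecific probe sets (median differences of these -0.496 and -0.231). The neuronal list's median level was 4.257 to 4.457 in these yolk sac arrays, not far above the nonspecific probe sets (3.70 to 3.83). That left little room for a fall with NTD there, so the neuronal difference rests mainly on the embryos. Lhx9 and Epha3 passed in 8 of the 12 fits with 1 array left out (highest adjusted p 0.0759 for each). The count was 0 without embryo MEHP 1, embryo MEHP 2, yolk sac MEHP 2 or yolk sac MEHP with NTD 3, and 9 without embryo MEHP 3 or embryo MEHP with NTD 2. It was 7 without yolk sac MEHP 1, 5 without yolk sac MEHP with NTD 1 and 6 without yolk sac MEHP with NTD 2. It was 6 without the arrays with high RNA 3'/5' ratios.

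**Figure D4:**
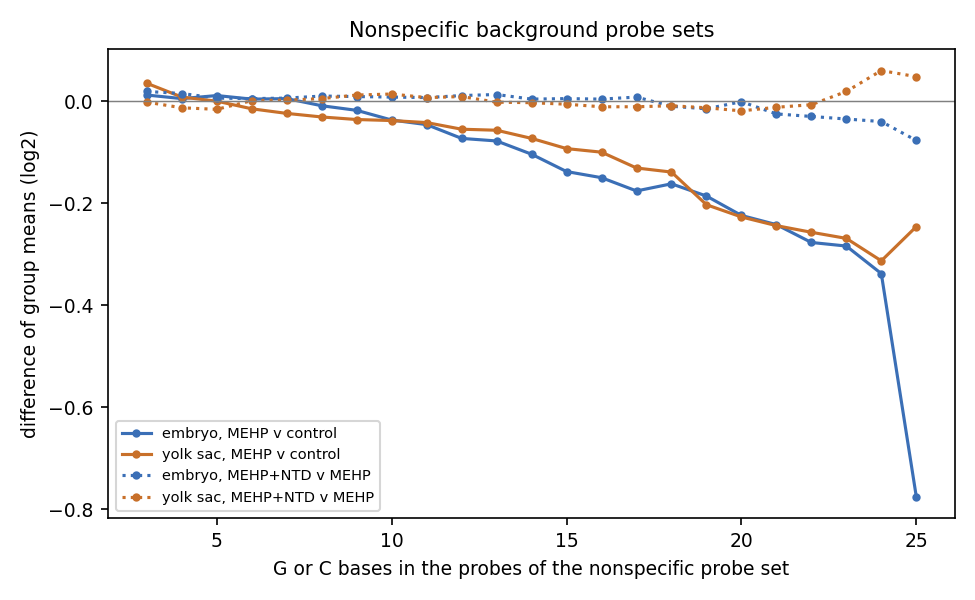
Change in log2 signal (vertical axis) of probe sets that match no mouse transcript against their number of G or C bases (horizontal axis), with solid lines for MEHP against control and dotted lines for MEHP with NTD against MEHP without, in embryos and yolk sacs. The solid lines fall with the number of G or C bases, to -0.34 in embryos and -0.31 in yolk sacs at 24 bases and -0.775 and -0.246 at 25, while the dotted lines stay between -0.08 and 0.06.

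The authors' own tests, on probe sets and with other groupings (6 MEHP arrays against 4 controls, and 4 arrays with NTD against 6 without), give 9067 probe sets of 45141 with a deposited FDR below 0.05 for exposure in embryo (4242 higher, 4825 lower) and 1821 in yolk sac (1003 higher, 818 lower). For NTD both tissues have 0 (smallest deposited FDR 0.191 in embryo and 0.237 in yolk sac), with 1888 and 3111 probe sets at an unadjusted p below 0.05.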

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

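Of the tests in this part, those on nuclear RNA, on posterior Hox genes and on other splits of the samples were set before their results were seen; all other tests on the first 3 patterns were chosen only after the result was seen.

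Most genes that fell in MEHP embryos are dim: 1011 of 1227 falls (82.4%) lie below the median gene's level, against 213 of 794 rises (26.8%). That level is a mean over the arrays of both tissues, so it is not a gene's level in embryos alone. Among brighter falls 189 of 216 passed after cyclic loess, and their median went from -0.38 to -0.43. The level-dependent shift between arrays that loess removes is thus not the cause of most of them. Loess moved brighter falls and brighter rises downward, which could only deepen these falls, so the test was weak. Of 581 brighter rises 297 passed after it (median 0.451 before and 0.384 after), so such a shift stays open for brighter rises. Lower nonspecific hybridization on the MEHP arrays could have lowered dim signals: the nonspecific probe sets with 16 to 24 G or C bases were lower by 0.22 on the log2 scale (-0.221) and every MEHP embryo array lay below every control array. For dim falls a level-dependent shift stays open, because 303 of 1011 passed after loess, the other 708 ending as their median moved from -0.339 (SD 0.067) to -0.255 (SD 0.07) with a median SE of 0.081 before and 0.08 after. Array order and exposure cannot be told apart, since 0 control arrays come after any MEHP array in the table, and MEHP itself stays among the open explanations.

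Expressed-sequence-tag and predicted transcripts are common among the rises with MEHP, with 205 of 794 (25.8%) in embryos and 23 of 40 in yolk sacs, against 18.5% of all genes and 25.3% of the embryo falls (311 of 1227), so in embryos the share is not particular to the rises. A level-dependent shift between arrays is argued against only in the form that cyclic loess removes. After it 162 of 205 embryo rises passed (median 0.66 before and 0.71 after). Loess moved dim embryo rises upward (median 0.612 before and 0.673 after), and 90.7% of all such transcripts are dim. It could therefore hardly have ended these rises, so the test was weak. Higher nonspecific signal at AT-rich probes is argued against by the nonspecific probe sets with 3 to 10 G or C bases, whose largest rise was 0.012 in embryos and 0.035 in yolk sacs. More nuclear RNA in the MEHP samples remains possible: Malat1 and Neat1 had a mean change of 0.392 over both tissues, but of Malat1 (0.48 ± 0.11 in embryo, 0.42 ± 0.18 in yolk sac) and Neat1 (0.05 ± 0.21 and 0.61 ± 0.27) the embryo value of Neat1 is within its error. A change in transcription with MEHP was not tested separately, and array order stays open as for the falls.

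Neuronal differentiation genes were lower in MEHP embryos with NTD than in those without. A single array as the cause is argued against by medians of -0.54 to -0.41 (nearest to 0: -0.41) with 1 array left out, and a smaller share of neural tissue as a whole by the neural progenitor list (median -0.031, SD 0.284). Slower development along the body axis could not be decided by 7 Hox genes of groups 9 and 10, since their median (-0.073) passed the bound set in advance against it by less than their spread (SD 0.5; 3 higher, 4 lower), with Hoxd10 (-1.22 ± 0.21, adjusted p = 0.159) lowest. Whether the defect goes with lower neuronal genes without MEHP cannot be told from 1 control embryo with NTD, in which the list lay 0.156 above the other controls, and array order and NTD cannot be told apart, since 0 of the MEHP embryo arrays without NTD come after any with NTD in the table. A lag of neuronal maturation in embryos with NTD is a hypothesis that may account for the pattern, and no test here parts it from the explanations left open.

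The effect of MEHP differed between embryo and yolk sac by a test of the difference for 16 genes, among them D10Ertd755e (1.874), 4732423E21Rik (1.198), Robo2 (1.045), Fgf9 (0.971), Dock4 (0.892) and Myh3 (0.84) with the higher effect in embryo, and F10 (-1.029), A2ml1 (-1.106), Mir1199 (-1.214), Creb3l3 (-1.333), Cidec (-1.365) and Cyp1a1 (-2.249) with the higher effect in yolk sac. Several of these sizes involve levels near or below the nonspecific probe sets, among them Cidec and Cyp1a1 in embryos, Robo2 in yolk sacs and control embryos, and D10Ertd755e, Fgf9 and 4732423E21Rik in yolk sacs. Of 100 splits drawn from 200 of the 12 arrays, 11 gave at least 16 genes, so chance cannot be excluded for this count. The highest other gave 3797 when the groups of 1 tissue were turned round, and by construction that split adds the effects of both tissues. Splits that keep the real groups of 1 tissue and mix the other carry the first tissue's own MEHP effect as a difference. The share of 11 in 100 therefore does not measure chance alone, and this test cannot decide the question.

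By the same test of the difference 12 lists were called for MEHP by camera at the preset correlation and 0 with an estimated one (smallest adjusted p 0.0965). At the preset correlation the cardiac, cholesterol, mesenchyme, heat shock, hypoxia, p53, parietal endoderm and xenobiotic calls each ended in some fit with 1 array left out. Without embryo control 3 hypoxia genes had a median of 0.012 (adjusted p = 0.904). The medians of the 12 with all arrays follow. Their medians were 0.119 for cardiac, -0.184 for cholesterol synthesis, 0.207 for mesenchyme, 0.066 for heat shock, 0.286 for Hox, 0.106 for hypoxia and glycolysis, 0.164 for neural progenitor, 0.16 for neural tube closure, 0.224 for neuronal, 0.107 for p53 target, 0.137 for parietal endoderm and -0.126 for xenobiotic metabolism genes.

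Between MEHP samples with and without NTD the effect differed between tissues by a test of the difference for 3 genes: Zfp462 (-0.647), Epha3 (-1.152) and Lhx9 (-1.646), the last 2 below the nonspecific probe sets in yolk sacs. Of 100 splits drawn from 200, 4 gave at least 3 genes, the real one included, a share narrowly under the bound of 0.05. The share over all 200 was not computed, the highest other count was 4, and 4 of the 12 fits with 1 array left out gave 0. Chance is therefore not firmly excluded for this count. Here too, splits that keep the real groups of 1 tissue carry that tissue's own NTD effect, so the share does not measure chance alone. The split with 1 tissue turned round, which was not drawn, gives 37, and by construction it adds the NTD effects of both tissues. The 14 lists called for this difference had medians of -0.166 for BMP response, 0.067 for cardiac, -0.088 for cell cycle, 0.049 for cholesterol synthesis, 0.152 for endocytosis, -0.291 for mesenchyme, 0.063 for fatty acid synthesis, -0.106 for Hox, -0.158 for imprinted, -0.265 for neural crest, -0.507 for neuronal, -0.335 for erythroid, -0.178 for retinoic acid and 0.159 for stress response genes. With an estimated correlation 2 of the 14 held, the neuronal (adjusted p = 0.00536) and neural crest lists (0.0102). Neuronal levels in yolk sacs left little room for a fall there. At the preset correlation the cardiac, cell cycle, cholesterol, fatty acid synthesis, Hox, imprinted, erythroid and retinoic acid calls each ended in some fit with 1 array left out. Erythroid genes, for example, had a camera adjusted p of 0.848 without yolk sac MEHP with NTD 1.

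For each comparison of 3 arrays with 3 there are 10 splits, too few for a share under 0.05, and the real split with its highest other gave 2021 and 1 genes for MEHP in embryo, 5 and 2 for NTD in MEHP embryos, 1549 and 2 for both in embryo, 65 and 0 for MEHP in yolk sac, 0 and 0 for NTD in MEHP yolk sacs, 494 and 0 for both in yolk sac, and 10657 and 1 for the tissues. As many genes as the real split came from 1 of the 10, the real one, in each of these except NTD in yolk sac, where it was 10 of 10.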

How the results depend on the processing

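Cyclic loess, the nonspecific level as a covariate, leaving out the arrays with high RNA 3'/5' ratios, the groups by the other table's sample headings and the exchange of control arrays were chosen only after the data were seen; the other tests were planned. Over all alternatives the named genes past the threshold kept direction and side in 3099 values, lost the threshold in 1807 and changed sign in 2, and named genes not past it stayed so in 7501 and passed in 109. Called lists kept their call in 774 values, lost it in 323 and turned in 5; lists not called stayed so in 2267, were called in 127 and turned in 4. The comparison of the control tissues gave 10657 genes, and 7939 to 10804 outside the settings named for it. Where no cause is given, the cause was not tested. By replicate number, no paired analysis was possible because the columns carry no replicate numbers. Pairing embryo and yolk sac arrays by place in the table was not run. The differences between tissues therefore rest on a fit that treats the tissues as independent, and how pairing would change them was not tested. Taking values from the other table was not run because they are identical. Dim genes lie near the nonspecific background, which limits what can be seen among them.

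Counts that moved by over 1.5 times are given as MEHP in embryo (2021), NTD in MEHP embryos (5), both in embryo (1549), MEHP in yolk sac (65), NTD in MEHP yolk sacs (0), both in yolk sac (494), difference for MEHP (16) and difference for NTD (3). Leaving out dim genes, which tests fewer genes, gave 488, 0 and 511 in embryo, 28 for MEHP in yolk sac, and 3 and 0 for the differences. Quantile normalization gave 0 for NTD in embryo and 10 for the MEHP difference. Trend and robust settings gave 8 for NTD in embryo, 199 for MEHP and 13 for NTD in yolk sac, and 7 for the NTD difference. All 20 arrays in 1 fit gave 3439, 20 and 3006 in embryo, and 191 for MEHP and 30 for NTD in yolk sac. The 6 arrays alone, with fewer samples for the spread, gave 0 for NTD and 348 for both in embryo, and 15 for both in yolk sac. Every probe set tested, which counts probe sets, gave 4053 for MEHP and 3074 for both in embryo, 389 and 1218 in yolk sac, 76 for the MEHP difference and 17955 for the tissues. The additive model, with 6 arrays against 4, gave 3078 for MEHP and 0 for NTD in embryo, and 353 and 2 in yolk sac.

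Cyclic loess gave 1094 for MEHP and 795 for both in embryo. The nonspecific level as a covariate, which parts exposed from control arrays by itself, gave 0, 0 and 0 in embryo, 0 for MEHP and 1 for both in yolk sac, and 5 for the NTD difference; under it Sox1 changed sign in MEHP embryos (-0.038) and Sesn1 in MEHP embryos with NTD (-0.059). Without the arrays with high RNA 3'/5' ratios there were 3309 for MEHP and 2 for NTD in embryo, 1 for MEHP and 32 for both in yolk sac, and 144 and 6 for the differences. Groups by the other table's headings gave 6521, 0 and 0 in embryo, 0, 6510 and 0 in yolk sac, 9662 and 10963 for the differences and 1092 for the tissues. Exchanging yolk sac control 3 with the control with NTD gave 2 for MEHP and 23 for both in yolk sac.

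With 1 array left out, a lone pair in a group being assumed to vary like the other groups, counts ranged from 286 to 2493, 0 to 7 and 270 to 1937 in embryo, 1 to 2, 0 to 1 and 18 to 192 in yolk sac, and 3 to 259 and 0 to 9 for the differences. Lists that turned with 1 array left out had these ranges of adjusted p: visceral endoderm (0.00574 to 0.833) and cholesterol genes (0.000722 to 0.765) for NTD in embryo, erythroid genes for NTD in yolk sac (7.3e-07 to 0.607), visceral endoderm genes for the MEHP difference (0.00887 to 0.992) and cholesterol genes for the NTD difference (0.000463 to 0.709). With members above the median gene's level alone, trophoblast genes turned in MEHP embryos (adjusted p = 0.612) and xenobiotic genes in the MEHP difference (0.269). Without the arrays with high RNA 3'/5' ratios, hypoxia genes turned in MEHP embryos with NTD (0.0221) and in the MEHP difference (0.702).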

Other observations

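Beyond the lists that were called, MEHP embryos without NTD differed from controls in a few Hedgehog pathway, somite and macrophage genes. Of 21 Hedgehog pathway genes 2 fell, among them Dhh (-0.44), 0 rose and 19 did not pass, with 2 falls adjusted over the list alone, and the list was not called (median -0.10, adjusted p = 0.242). Of 29 somite genes Myf5 rose (1.17 ± 0.22) and 4 fell, among them Scx (-0.43), Wnt3a (-0.34) and Pax9 (-0.32), with 1 rise and 5 falls adjusted over the list alone (median -0.10, adjusted p = 0.508). Of 21 macrophage genes Mpo (-0.36) and Cd14 (-0.32) fell, by both counts (median -0.12, adjusted p = 0.107).

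The effects of MEHP in the samples without NTD were correlated between embryo and yolk sac across genes, which are not independent replicates: r was 0.447 over all 20794 genes, 0.659 over 3856 expressed-sequence-tag and predicted transcripts and 0.699 over the 2021 genes past the threshold in embryo (0.438, 0.649 and 0.688 after cyclic loess). The tissues share no arrays, though all control arrays precede all MEHP arrays in both.

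The 1 control array with NTD of each tissue was set against the mean of the 3 controls, with its percentile among 10000 random lists and no test. In embryo the sex-linked (0.926, percentile 100), Hox (0.161, 99.85), neuronal (0.156, 99.92) and somite lists (0.138, 99.91) lay highest, and the hypoxia (-0.11, 0), erythroid (-0.06, 0.08) and visceral endoderm lists (-0.05, 0.03) lowest. In yolk sac the sex-linked (2.384, 100), BMP (0.067, 99.7), mesenchyme (0.064, 99.94) and visceral endoderm lists (0.06, 99.95) lay highest, and the macrophage (-0.28, 0), erythroid (-0.19, 0) and trophoblast lists (-0.14, 0.01) lowest.

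Of 20 arrays 8 carry both Xist and the Y-linked Ddx3y, 10 carry Xist alone and 2 carry Ddx3y alone, embryo control 3 and the yolk sac control with NTD. Embryo MEHP 2, for example, had Xist at 11.116 and Ddx3y at 7.856. Embryo control 3 had Xist at 5.52, and embryo MEHP 1 had Ddx3y at 3.719. Carrying both argues against a single conceptus in those 8 arrays. In table order the classes of embryo and yolk sac arrays match at 8 of 10 places, and at 10 of 10 if yolk sac control 3 and the yolk sac control with NTD were exchanged. It is also 10 of 10 if embryo control 3 and the embryo control with NTD were exchanged instead. The mismatch does not depend on table order: the single control with NTD carries both in embryo and Ddx3y alone in yolk sac. Among controls without NTD, Ddx3y alone occurs in embryo and not in yolk sac. Whether the tissues of a group come from the same conceptuses is not given in the sources used here. If they do, labels of control arrays are in doubt. So are then the values of a single control with NTD and the comparisons with controls without NTD.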
